A study of Homo sapiens with 4 samples.

How the data were processed

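RNA sequencing measured gene expression in 4 libraries of T47D cells, an established luminal breast cancer cell line that expresses the estrogen receptor. Per the labels, 2 libraries came from cells kept for 24 h in medium with MK2206, an allosteric inhibitor of the AKT kinases, and 2 from cells kept in medium with DMSO, the vehicle. Total RNA was extracted with a column kit and libraries were made with a stranded kit that selects polyadenylated RNA, per the labels' protocols. The dose of MK2206 is not given in the sources used here. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

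The submitters' processing notes name FastQC 0.10.0, TopHat and the genome build hg19. The program that made the expression values is not given in the sources used here. The authors deposited 1 table with a row for each RefSeq transcript, a gene symbol and a value for each library. The unit is not stated in the header. The deposited values were read as FPKM (fragments or reads per kilobase of transcript and per M mapped), because they are not whole, sum to 553060 to 563360 in each library, and, multiplied by transcript length, fall near whole multiples of 1 step per library in low genes. Reads and fragments cannot be told apart from the values. The table holds 37542 rows, of which 31839 are protein-coding (NM) and 5703 non-coding (NR) transcripts. The column of MK2206 replicate 1 was matched to its sample by library number, since the title gives both MK2206 libraries the replicate number 2 and the column name gives this one 1. In 798 rows there is no gene symbol, and these rows hold 2.83% to 3.85% of the summed FPKM. Most of that share lies in a single row, a copy of MIR1244-1, with 11991 to 18018 FPKM of 15680 to 21696 FPKM. The rows without a symbol stayed out of the gene test and were tested apart. Rows of 1 symbol were summed, which gave 22727 genes. The files hold no coordinates, and the reference annotation at hand belongs to another build (GRCh38), so it served only for names, transcript lengths and GC content, and no positions are given. Genes of the lists that the table does not hold under their symbol or an older one, among them the HLA genes, TUBB and the mitochondrially encoded genes, were not analysed here.

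The depth was estimated from the steps in the low values of 11421 genes with 1 transcript of at least 1000 nt. With 200 nt subtracted from each length, it came to 43.67 M reads or fragments for MK2206 replicate 1, 36.9 M for MK2206 replicate 2, 49.5 M for DMSO replicate 1 and 34.72 M for DMSO replicate 2. Between 73.6% and 76.06% of the low values lay within 0.15 of a whole multiple, where 30.0% is the share by chance. These figures are estimates, since the counts themselves are not used here. At these depths 1 FPKM of a transcript of 2000 nt stands for 62.5 to 89.1 reads or fragments. On simulated whole counts for the same genes at 3 depths the estimate missed the true depth by at most 0.1%. The simulation used the same lengths and the same 200 nt, so it cannot show errors that come from these.

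Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, 12057 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an empirical Bayes trend of the variance on the mean level, 2 residual degrees of freedom and 3.71 prior degrees of freedom. Every log2 change is MK2206 minus DMSO on that scale, which understates the change of low genes, and ratios are of mean FPKM. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, two-sided, adjusted over the 26 lists with at least 5 tested members. The 22 gene lists and 7 check lists (markers of other cell types, histone, mitochondrial, handling and housekeeping genes), the threshold, the filter and the rule for named genes were fixed before the data were examined. The rule named the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean level at or above the median of the genes tested and no overlap between the groups. It also named the 2 members of each gene list with the smallest p, or 4 where the list passed, and a fixed set of genes around AKT and the estrogen receptor. Y-linked genes and XIST were left out, and some genes that the rule takes are not reported here. Because the first part of the rule returned small RNA genes, the same part was repeated without them, a choice made after the values were seen. Genes called small RNA here are microRNA, snoRNA, scaRNA and similar genes by symbol, and transcripts of at most 200 nt.

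On simulated libraries with the levels and spreads of the real ones and 12057 genes, 50 were changed at each of 4 fold sizes and 40 others were planted as a list with a log2 change of 0.5. The test for MK2206 against DMSO recovered 24% of the genes changed 1.25-fold, 58% at 1.5-fold, 90% at 2-fold and 94% at 3-fold, with 4 calls among 11817 unchanged genes. None of 200 random lists of 40 genes passed camera there, and the planted list did. The simulated genes varied independently of each other, so this does not show how camera treats lists whose genes vary together. Far fewer genes were changed there than the 59.6% called in the real libraries, so the recovery at the adjusted threshold may differ. A planted length trend with a slope of 0.47 fell to -0.051 after the trend correction.

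The alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, quantile normalization, median centring, limma without the trend, each transcript row as its own feature, stricter thresholds, each library left out in turn, and, for the lists, camera with an estimated correlation and the fry rotation test. Added after seeing the data were a block on the replicate number in the column names, a test without small RNA genes, a test of protein-coding transcripts alone, and removal of each library's trend with transcript length and GC content, for which 96.0% of the tested genes had a length. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so few lists or families can pass it. Figures were drawn with matplotlib 3.10.9.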

Results

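The series asks how messenger RNA levels in T47D breast cancer cells differ after 24 h with the AKT inhibitor MK2206 from those after 24 h with DMSO. There were 2 libraries per group, with an estimated depth of 34.72 to 49.5 M reads or fragments. Between 11749 and 11980 genes reached 1 FPKM in a library. The 10 most abundant genes held 9.52% to 10.4% of the summed FPKM of the named genes. Across the tested genes, log2 values correlated with a Pearson r of 0.982 between the MK2206 libraries and 0.979 between the DMSO libraries, and with an r of 0.949 to 0.955 between libraries of different groups. Genes are not independent replicates, so these correlations carry no p-value. The variance between replicates was 3.83 times the counting noise in the MK2206 pair and 3.62 times in the DMSO pair, so neither pair behaved as 1 library deposited in duplicate.

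With MK2206, genes of DNA replication and mitosis fell together in camera. So did MYC and ribosome biogenesis, glycolysis, fatty acid and cholesterol synthesis genes. With an estimated correlation camera gave these lists adjusted p = 0.397 to 0.462. Target genes of the FOXO transcription factors, lysosome and autophagy genes, ribosomal protein genes and histone genes rose (camera; adjusted p = 0.397 to 0.558 with an estimated correlation). The FOXO target gene KLHL24 rose 7.77-fold and the receptor gene ERBB3 1.86-fold, with log2 changes of 2.63 (SE 0.054, n = 2) and 0.88 (SE 0.042, n = 2), whereas the replication gene RRM2 stood at 0.197 of its DMSO level, a log2 change of -2.28 (SE 0.059, n = 2). In limma's test 7185 of the 12057 genes tested changed, or 59.6%, of which 3732 rose and 3453 fell. That share depended on the filter and on summing rows to genes. With no filter on low values 6872 of 18445 genes changed, and by transcript row 5696 of 16511 rows did. On the log2(FPKM + 1) scale 493 of them changed by at least 2-fold, 161 up and 332 down, and by the ratio of mean FPKM 800 did, 339 up and 461 down, with 19 more listed near 0 in one group and given no ratio. Leaving out small RNA genes, a choice made after the values were seen, gave 7591 changed genes among 11912.

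DNA replication and E2F target genes fell as a group. All 44 members of the list were tested and all 44 fell, also adjusted over the list alone, with a median log2 change of -1.43 (camera, adjusted p = 1.5e-22). With an estimated correlation, which leaves camera 2 degrees of freedom here, the list did not pass (adjusted p = 0.398). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, stood at 91.0 ± 4.95 FPKM (SD, n = 2) in DMSO and at 17.9 ± 0.721 FPKM (SD, n = 2) in MK2206, a log2 change of -2.28 with a standard error of 0.059 (limma, adjusted p = 3.4e-05). CDC6, which loads the replicative helicase, stood at 0.232 of its DMSO level, TYMS, which makes thymidylate, at 0.278, and the helicase subunit MCM3 at 0.365. MCM10 and CDC45, named for the size of their fall, stood at 0.202 and 0.223 of their DMSO levels.

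Mitosis genes moved the same way. All 40 were tested and all 40 fell, also adjusted over the list alone, with a median log2 change of -1.39 (camera, adjusted p = 8.7e-21). The adjusted p was 0.397 with an estimated correlation. MYBL2, a transcription factor of proliferating cells, went from 104.9 ± 0.0523 FPKM (SD, n = 2) in DMSO to 22.7 ± 0.985 FPKM (SD, n = 2) in MK2206 (limma, log2 change -2.16, adjusted p = 3.4e-05). The kinase AURKB stood at 0.256 of its DMSO level, the ubiquitin-conjugating enzyme gene UBE2C at 0.351 and the topoisomerase TOP2A at 0.358. FAM111B, outside the lists, stood at 0.253 of its DMSO level. Among 21 tested D-type cyclins, CDK inhibitors and related genes, 7 rose and 11 fell, or 7 and 14 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.063). It did pass without DMSO replicate 1 (adjusted p = 0.013) and without DMSO replicate 2 (adjusted p = 0.035). CCND3 stood at 0.362 and CKS1B at 0.460 of their DMSO levels.

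FOXO target genes rose. Of 26 tested members 21 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone, and the median log2 change was 0.65 (camera, adjusted p = 4.3e-07). The adjusted p was 0.397 with an estimated correlation. KLHL24 went from 3.23 ± 0.0687 FPKM (SD, n = 2) in DMSO to 25.1 ± 0.717 FPKM (SD, n = 2) in MK2206, a log2 change of 2.63 with a standard error of 0.054 (limma, adjusted p = 3.4e-05). PIK3IP1, which encodes an inhibitor of PI3K, rose 5.59-fold, the cyclin gene CCNG2 rose 3.76-fold and the mRNA decay factor ZFP36L2 rose 2.72-fold. Per-library values of several of these genes are plotted beside genes that fell.

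**Figure D1:**
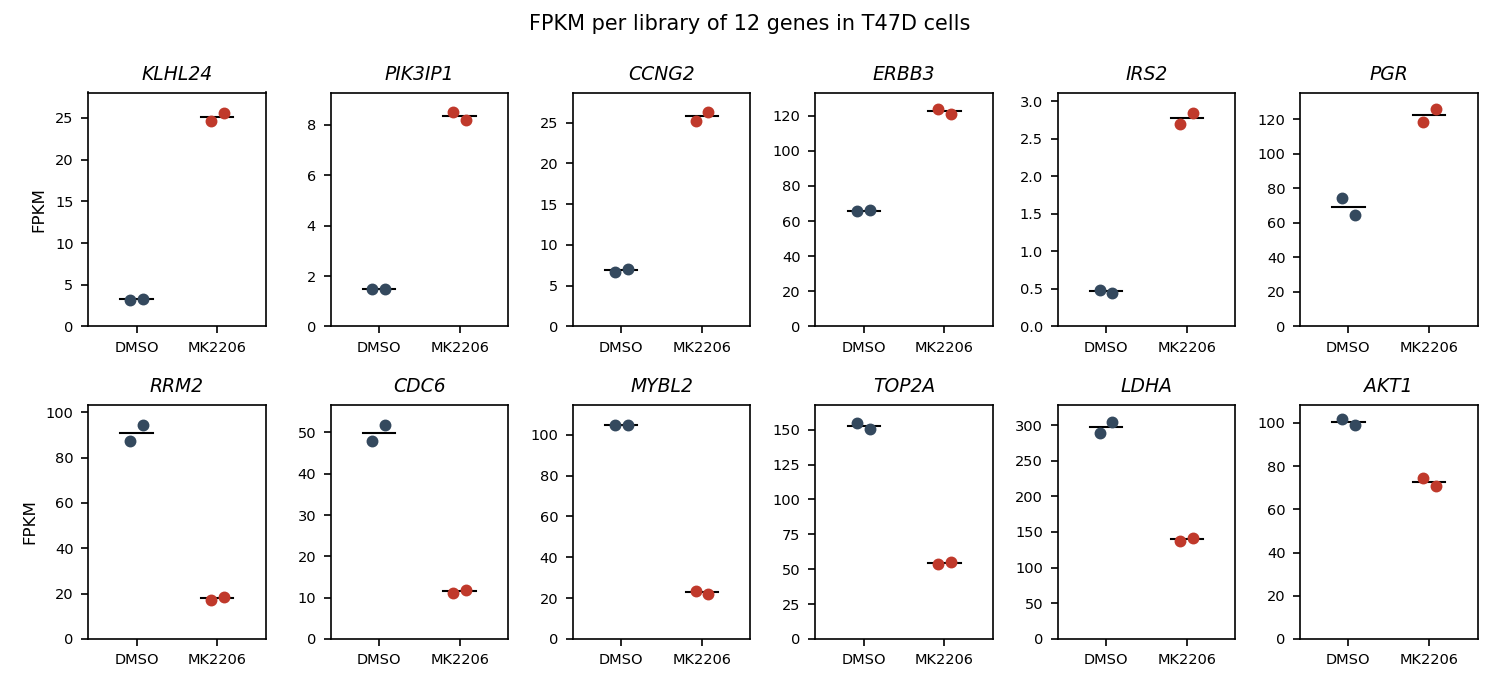
FPKM (y axis, linear, from 0) of 12 genes in each of the 4 libraries, grouped as DMSO and MK2206 (x axis). Points are libraries and bars are group means; in each of the 12 genes the MK2206 libraries lie apart from the DMSO libraries, for example 24.6 and 25.6 FPKM against 3.18 and 3.28 FPKM for KLHL24.

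Lysosome and autophagy genes also rose. Of 37 tested members 28 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone (camera, median log2 change 0.38, adjusted p = 3.1e-06). With an estimated correlation the adjusted p was 0.398. GABARAPL1, an autophagosome protein gene, rose 3.07-fold, and the lysosomal protease genes CTSF, TPP1 and CTSA rose 2.24-fold, 2.17-fold and 1.75-fold. Outside the lists, GPNMB rose 5.07-fold, CALCOCO1 rose 4.36-fold and the ferritin light chain gene FTL rose 3.57-fold. FTL has processed pseudogenes that can share its reads, so its value is uncertain.

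The list of MYC and ribosome biogenesis genes and that of cytosolic ribosomal protein genes moved in opposite directions. In the list of MYC and ribosome biogenesis genes 0 of 35 members rose, 30 fell and 5 did not pass, or 31 fell adjusted over the list alone (camera, median log2 change -0.50, adjusted p = 1.2e-09), and the adjusted p was 0.397 with an estimated correlation. HSPD1, NOP56, RRS1 and NOLC1 stood at 0.521, 0.549, 0.550 and 0.610 of their DMSO levels. Of 46 tested cytosolic ribosomal protein genes 32 rose, 1 fell and 13 did not pass, or 33 and 2 adjusted over the list alone, by a small amount each (camera, median log2 change 0.17, adjusted p = 5.6e-05). The adjusted p was 0.558 with an estimated correlation. With quantile normalization the median log2 change was 0.10, and 24 rose and 6 fell. RPL23 rose 1.33-fold, RPL15 and RPS27 rose 1.29-fold and 1.28-fold, and RPL18 rose 1.23-fold. Ribosomal protein genes have many processed pseudogenes, and their values are uncertain for that reason.

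Metabolic lists fell. Among 27 tested glycolysis and glucose uptake genes 4 rose, 21 fell and 2 did not pass, or 5 and 21 adjusted over the list alone (camera, median log2 change -0.38, adjusted p = 2.4e-04, and adjusted p = 0.462 with an estimated correlation). PFKP, TPI1 and LDHA, enzymes of glycolysis and lactate formation, stood at 0.426, 0.618 and 0.471 of their DMSO levels, and the regulator PFKFB3 rose 1.64-fold. Of 18 fatty acid synthesis genes 0 rose, 11 fell and 7 did not pass, with the same counts adjusted over the list alone (camera, median log2 change -0.41, adjusted p = 0.0028, and adjusted p = 0.397 with an estimated correlation). ACLY, FADS1, FADS2 and ELOVL6 stood at 0.648, 0.595, 0.572 and 0.497 of their DMSO levels. Of 24 cholesterol synthesis genes 3 rose, 14 fell and 7 did not pass, or 4 and 14 adjusted over the list alone (camera, median log2 change -0.29, adjusted p = 0.0048, and adjusted p = 0.397 with an estimated correlation). EBP, ACAT2, DHCR7 and FDPS stood at 0.493, 0.492, 0.676 and 0.716 of their DMSO levels. The list of ATF4 and amino acid genes split. Of its 34 tested members 7 rose, 21 fell and 6 did not pass, or 7 and 22 adjusted over the list alone (camera, median log2 change -0.30, adjusted p = 0.0048, and adjusted p = 0.398 with an estimated correlation). The serine synthesis gene PSAT1 and the amino acid transporter gene SLC7A5 stood at 0.328 and 0.458 of their DMSO levels, whereas the stress response genes NUPR1 and DDIT3 rose 2.79-fold and 2.61-fold.

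**Figure D2:**
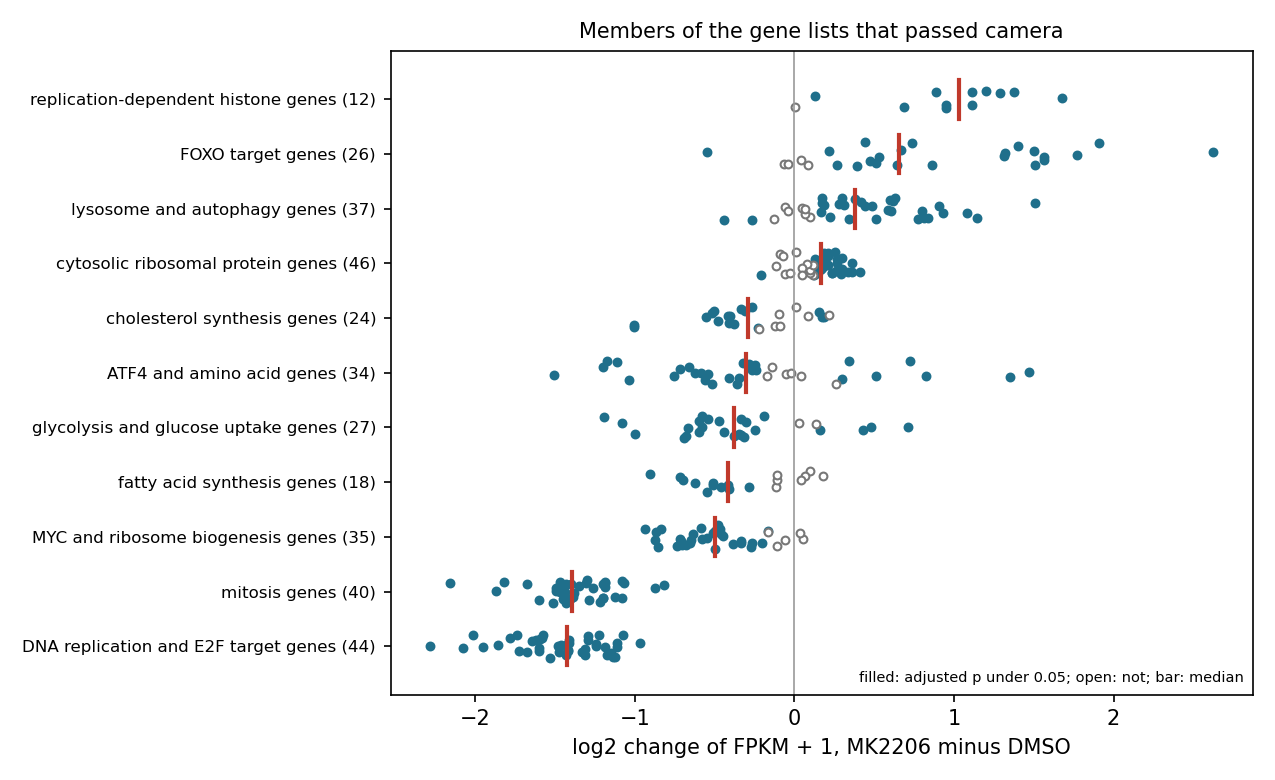
Log2 change of FPKM + 1, MK2206 minus DMSO (x axis), for the members of each list that passed camera (y axis, number tested in parentheses). Each point is a gene, filled where its adjusted p was under 0.05 and open where not, and red bars are medians, from -1.43 for DNA replication genes to 1.03 for histone genes.

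The receptor tyrosine kinase list did not pass as a whole, but its members changed in both directions. Of 20 tested members 10 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.178). The 4 that fell, named after their values were seen, were FGFR4, EPHA2, RET and FGFR3. They stood at 0.497, 0.532, 0.537 and 0.629 of their DMSO levels. ERBB3 went from 65.9 ± 0.242 FPKM (SD, n = 2) in DMSO to 122.4 ± 2.13 FPKM (SD, n = 2) in MK2206 (limma, log2 change 0.88, standard error 0.042, adjusted p = 5.9e-05). IRS2, an adaptor of the insulin receptor, rose 5.94-fold from 0.467 FPKM, and INSR rose 2.31-fold from 0.570 FPKM. IGF1R stood at 9.30 ± 0.781 FPKM in DMSO and 10.6 ± 0.0557 FPKM in MK2206 (SD, n = 2 each; limma, adjusted p = 0.069), and passed without DMSO replicate 1 (adjusted p = 0.019), without small RNA genes (0.042), among protein-coding transcripts alone (0.044), with a replicate block (0.044) and with length and GC trends removed (0.0079). Of 27 PI3K, AKT and mTOR pathway genes 7 rose, 10 fell and 10 did not pass, also adjusted over the list alone (camera, adjusted p = 0.972), and the direction turned without MK2206 replicate 2 or DMSO replicate 2 (adjusted p = 0.962 and 0.920). DEPTOR, an mTOR inhibitor gene, rose 2.30-fold, and the translation repressor gene EIF4EBP1 stood at 0.494 of its DMSO level. Of the drug's targets, AKT1 stood at 0.724 of its DMSO level (limma, adjusted p = 6.3e-04), and AKT2 stood at 1.09 times its DMSO level and did not pass (limma, adjusted p = 0.106), but did with a replicate block (0.031) and with length and GC trends removed (0.014). ERK pathway output genes counted 11 that rose and 4 that fell among 16 tested, or 11 and 5 adjusted over the list alone (camera, adjusted p = 0.077). That list passed without DMSO replicate 1 (adjusted p = 0.014) and without DMSO replicate 2 (adjusted p = 0.022), and with no filter on low values its median log2 change was 0.016, against 0.41 (adjusted p = 0.648). PHLDA1 rose 2.39-fold and PHLDA2 stood at 0.270 of its DMSO level. MYC rose 1.49-fold.

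Among 32 estrogen receptor target genes 15 rose, 7 fell and 10 did not pass, and among 28 luminal identity genes 14 rose, 5 fell and 9 did not pass, each with the same counts adjusted over the list alone (camera, adjusted p = 0.287 and 0.156). PGR, the progesterone receptor gene, went from 69.3 ± 7.01 FPKM (SD, n = 2) to 122.3 ± 5.24 FPKM (SD, n = 2), a log2 change of 0.81 (limma, adjusted p = 5.0e-04). The luminal transcription factor genes FOXA1 and GATA3 rose 1.42-fold and 1.38-fold, STC2 rose 1.43-fold, and OLFM1 stood at 0.572 of its DMSO level. GREB1 stood at 51.4 ± 1.93 FPKM in DMSO and 54.99 ± 1.98 FPKM in MK2206 (SD, n = 2 each) and did not pass (limma, adjusted p = 0.162). It passed with quantile normalization, where its log2 change was 0.18 against 0.096 (adjusted p = 0.041), with a replicate block (0.031) and with length and GC trends removed (0.028). ESR1, TFF1 and CCND1 passed with small ratios of 1.14, 0.856 and 0.892 (limma, adjusted p = 0.031, 0.016 and 0.020). ESR1 did not pass without MK2206 replicate 2, DMSO replicate 1 or DMSO replicate 2 (adjusted p = 0.153, 0.083 and 0.064), and TFF1 did not pass without the same libraries (adjusted p = 0.070, 0.068 and 0.053). CCND1 did not pass without any one of the 4 libraries (adjusted p = 0.062 to 0.107). Testing each transcript row ended the calls of ESR1 and TFF1 (adjusted p = 0.240 and 0.053), no filter on low values that of ESR1 (adjusted p = 0.055) and quantile normalization that of CCND1 (adjusted p = 0.141).

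The remaining gene lists did not pass camera. BCL2 family genes counted 6 that rose and 5 that fell among 13 tested (adjusted p = 0.672), with BBC3 at 3.15 times and BMF at 2.33 times their DMSO levels. p53 target genes counted 7 and 6 among 23 (adjusted p = 0.726), with TP53INP1 at 2.88 times and AEN at 0.408 of their DMSO levels. Hypoxia genes counted 11 and 7 among 24 (adjusted p = 0.178), or 12 and 7 adjusted over the list alone, with NDRG1 at 3.80 times and MXI1 at 2.83 times their DMSO levels. Histone methylation and acetylation enzymes counted 12 and 11 among 37 (adjusted p = 0.969), or 13 and 12 adjusted over the list alone, with a median log2 change of 0.016, a mean of -0.026 and a camera direction of down, which turned without MK2206 replicate 2 or DMSO replicate 1 (adjusted p = 0.962 and 0.805), and with EZH2 at 0.384 and WHSC1 at 0.468 of their DMSO levels. MicroRNA processing genes counted 3 and 9 among 20 (adjusted p = 0.245), with RAN at 0.645 and AGO2 at 0.614 of their DMSO levels. Interferon response genes counted 10 and 2 among 24 (adjusted p = 0.103), with OAS3 at 0.326 and IFI35 at 1.43 times their DMSO levels, and passed without MK2206 replicate 1 (adjusted p = 0.0040). In the interferon list, IFIT1, MX1, ISG15 and OAS1 lay above both DMSO libraries in MK2206 replicate 2 and below both in MK2206 replicate 1. IFIT1, for example, stood at 4.97 FPKM in MK2206 replicate 2, 2.18 in MK2206 replicate 1, and 2.93 and 2.31 in DMSO. None of them passed (limma). OAS2 and STAT2, among those that rose, were higher in both MK2206 libraries. Where no other count is given, those adjusted over the list alone were the same.

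Check lists gave the following values. Replication-dependent histone genes, whose main transcripts carry no poly(A) tail, rose in 11 of 12 tested members, also adjusted over the list alone (camera, median log2 change 1.03, adjusted p = 2.2e-05). The other 7 of the 19 listed lay below 1 FPKM in every library. The histone list did not pass with an estimated correlation (camera, adjusted p = 0.398). HIST1H2AC rose 3.29-fold and HIST1H1C rose 2.63-fold, and near-identical copies make single histone genes uncertain. Housekeeping genes counted 3 that rose and 8 that fell among 17 (camera, adjusted p = 0.065), with TUBA1B at 0.342 and ACTB at 0.677 of their DMSO levels and EEF1A1 at 1.39 times, and the list passed without DMSO replicate 1 (adjusted p = 0.046). Of 11 immediate early and heat shock genes 4 rose and 6 fell (camera, adjusted p = 0.287). All the heat shock genes tested fell, with HSPH1, HSPA8 and HSP90AA1 at 0.423, 0.531 and 0.583 of their DMSO levels. The 4 that rose were the immediate early genes FOS, JUN, JUNB and JUND, whereas ATF3 fell. The list value thus joins genes that moved in opposite directions. Basal and mesenchymal markers were mostly low, with 17 of 24 below 1 FPKM in every library, and 1 of the 6 tested rose and 1 fell (camera, adjusted p = 0.969). Their median log2 change was -0.026, their mean 0.0022 and their camera direction down, which turned without MK2206 replicate 2 or DMSO replicate 2 (adjusted p = 0.969 and 0.991). Of the stromal and endothelial markers 11 of 14 lay below 1 FPKM in every library, and of the 3 tested, too few for a list test, TAGLN stood at 1.55 times, ACTA2 at 0.878 and COL1A1 at 0.849 of their DMSO levels. All 14 immune markers lay below 1 FPKM in every library, the highest value being 0.673 FPKM. Members of the check lists were chosen for these sentences after their values were seen.

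The largest changes by size belonged to small RNA genes, most of them listed at 0 in the libraries of one group, for which no fold is given. MIR1260B was listed at 295.4 and 117.1 FPKM in MK2206 and at 0 in both DMSO libraries, and MIR1304 at 136.5 and 388.9 FPKM in DMSO and at 0 in both MK2206 libraries. The others were SNORD116-20, SNORD19B, MIR3916 and MIR210, listed at 0 in DMSO, MIR4724, listed at 110.3 and 100.6 FPKM in MK2206 and below 0.01 FPKM in DMSO, and SNORD116-4, SNORD88B, MIR647 and SNORD116-1, listed at 0 in MK2206. BCYRN1 went from 132.0 ± 16.6 FPKM (SD, n = 2) in DMSO to 23.6 ± 3.86 FPKM (SD, n = 2) in MK2206. In all, 38 of 145 small RNA genes tested passed (limma), 14 up and 24 down, and 69 of the 145 were listed at or near 0, under 0.01 FPKM, in 1 library of a group and above that in the other.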

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

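The test in this part was chosen after the data were seen. The table holds rows without a gene symbol, which the gene comparison leaves out, and 177 of them were tested with limma on the same scale, within the test of all rows. With MK2206, 16 of these rows rose above their level in the DMSO libraries and 20 fell. A further copy of the histone gene H2AC19, named by its transcript accession, was listed at 73.0 and 66.6 FPKM in MK2206 and at 30.5 and 29.9 FPKM in DMSO (log2 change 1.18, adjusted p = 0.0021), and a copy of H4C15 at 30.5 and 27.5 FPKM against 16.5 and 18.0 FPKM (log2 change 0.71, adjusted p = 0.0078). A copy of BOLA2 was listed at 13.1 and 11.5 FPKM in MK2206 and at 22.04 and 20.93 FPKM in DMSO (log2 change -0.76, adjusted p = 0.0071). Of the 177 transcripts 79 are marked as further copies, as are 13 of the 36 that passed; copies share reads with their partner, so their values are uncertain. The smallest adjusted p belonged to a transcript that is not marked as a copy and was not matched to a gene here, listed at 3.26 and 3.18 FPKM in MK2206 and at 12.8 and 11.5 FPKM in DMSO (log2 change -1.64, adjusted p = 0.0020).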

How the results depend on the processing

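The replicate block, the fits without small RNA genes, of protein-coding transcripts alone and with length and GC trends removed were chosen after seeing the data. The alternatives planned for a table of counts (another count test, other size factors, total-count scaling, no and a stricter count filter) were not run, since the values are FPKM. Over the settings that kept the threshold, between 5318 (of 8813 tested) and 8359 genes changed, against 7185. The share was lower with no filter (6872 of 18445) and by transcript row (5696 of 16511). Without 1 library, where the lone library is assumed to vary like the other group, no shared call turned. In other settings shared calls kept direction except 37 by transcript row and 1 among protein-coding transcripts. Asking for at least 2-fold on the log2(FPKM + 1) scale left 493 genes, 161 up and 332 down, by the threshold's own construction. Quantile normalization and median centring moved the median of all genes by under 0.1 and the share of calls that rose to 52.8% and 49.6%, against 51.9%, and the ribosomal protein median to 0.10 and 0.15, against 0.17. Replicate numbers follow the column names. In the titles both MK2206 libraries carry the number 2, so the labels name no pairs for the replicate block to fit. Same-numbered libraries still deviated together across genes, with a Pearson r of 0.19 and a Spearman rho of 0.45. With the replicate block, at 1 residual degree of freedom, 8359 genes passed. A batch shared by same-numbered libraries was not tested, and the main test does not model it. Of 93 named genes, 74 were tested in all 16 settings and the others in 12 or more. Of the 93, 87 kept direction and side of the threshold wherever they were tested. In some settings 3 (ESR1, TFF1, CCND1) lost the call and 3 (AKT2, GREB1, IGF1R) gained it, and 0 reversed. The genes that lost or gained a call all belong to the set fixed in advance. Most others were named for large changes or small p in these same libraries, so their calls tend to hold when the same values are refitted.

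Of 26 lists, 11 passed. With an estimated correlation 0 passed, with adjusted p = 0.397 for FOXO, mitosis, cholesterol, fatty acid and ribosome biogenesis genes, 0.398 for DNA replication, ATF4, lysosome and histone genes, 0.462 for glycolysis and 0.558 for ribosomal protein genes; unadjusted, p was 0.016 for mitosis and 0.042 for ribosome biogenesis genes and above 0.05 for the others. The fry test, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, passed 21, adding adjusted p = 0.0093 for receptor kinases, 0.032 for estrogen receptor targets, 0.0037 for luminal genes, 0.010 for D-type cyclins and for hypoxia genes, 0.015 for ERK output, 0.027 for BCL2 family, 0.0086 for microRNA processing, and 0.0049 for handling and for housekeeping genes, and turned the basal markers (0.587). Under camera the 11 lists passed in all other settings. D-type cyclins also passed at a mean of 5 FPKM (0.045) and without small RNA genes (0.048), ERK output with trends removed (0.049; 0.648 with no filter), and housekeeping genes with no filter (0.018), quantile normalization (0.045), the replicate block (0.048) and trends removed (0.047). The direction turned, never past the threshold, for PI3K pathway genes with no filter (0.964) and by transcript row (0.833), p53 targets with no filter (0.837), basal markers with no filter (0.520), BCL2 family genes at a mean of 5 FPKM (0.991), and histone enzymes with trends removed (0.984). Leaving out 1 library gave ranges of 0.0040 to 0.581 for interferon, 0.013 to 0.067 for D-type cyclins, 0.014 to 0.117 for ERK output, 0.046 to 0.076 for housekeeping, 0.802 to 0.962 for PI3K pathway, 0.465 to 0.962 for histone enzymes and 0.851 to 0.991 for basal markers; the direction of the PI3K pathway and basal markers turned without MK2206 replicate 2 and DMSO replicate 2, and that of histone enzymes without MK2206 replicate 2 and DMSO replicate 1. Apart from these constructions, the cause was not tested. At 2000 nt 1 FPKM stands for 62.5 to 89.1 reads or fragments, and the variance between replicates was 3.62 to 3.83 times the counting noise among the 6501 and 6610 genes with at least 50 estimated reads; lower genes were not compared in this way.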

Other observations

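All tests of gene families in this part, and those of depth, of RNA without a poly(A) tail and of short transcripts, were chosen after the results were seen; the test of length and GC trends was set before its result. Beyond the lists, 20 families of genes that share a symbol stem were tested with camera, adjusted over the 20, and 15 passed. A stem can also take in related genes that are not subunits or factors of the kind named. The translation repressor gene EIF4EBP1, for example, was counted with the initiation factors. The family names are therefore approximate. Proteasome subunit genes fell in 35 of 46 tested members and rose in 1 (median log2 change -0.36, adjusted p = 2.4e-08). Nucleoporin genes fell in 17 of 19 (median log2 change -0.64, adjusted p = 2.4e-07) and tubulin genes in 15 of 18 (median log2 change -0.74, adjusted p = 1.3e-06). Genes of the CCT chaperonin, which folds tubulin and actin, fell in 8 of 9, importin genes in 10 of 14, spliceosome genes in 15 of 20 and mitochondrial ribosomal protein genes in 45 of 77 (adjusted p = 0.0010, 5.8e-04, 1.0e-04 and 4.8e-05). Zinc finger genes of the ZNF series, most of which encode transcription factors, went the other way, with 222 of 426 up and 45 down (median log2 change 0.21, adjusted p = 7.0e-06), as did RAB genes of vesicle traffic, with 34 of 60 up and 7 down (adjusted p = 0.0010), and subunit genes of the lysosomal proton pump, with 11 of 18 up and 2 down (adjusted p = 0.045). Subunit genes of respiratory complex I and ATP synthase, translation initiation factor, kinesin and heat shock protein genes also passed, with negative medians (adjusted p = 0.0012, 0.0016, 0.017, 4.0e-04 and 0.021). The 5 that did not pass were SLC transporter genes, with 50 up and 77 down of 203, USP ubiquitin protease genes, with 13 up and 11 down of 49, elongation factor genes, with 3 up and 4 down of 10, keratin genes, with 6 up and 2 down of 11, and MAGE genes, with 1 up of 5 (adjusted p = 0.221, 0.937, 0.724, 0.179 and 0.284). Of the 20 families 9 hold genes of the lists fixed earlier, among them kinesin genes of mitosis and pump genes of the lysosome, so they partly repeat those results. Without such genes 14 passed: the proton pump and heat shock families did not (adjusted p = 0.064 and 0.138), and keratin genes did (adjusted p = 0.045). With an estimated correlation, which leaves camera 2 degrees of freedom here, no family passed, the lowest adjusted p being 0.166. The 15 that passed at the preset correlation kept the sign of their median under quantile normalization and median centring.

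Of the genes tested 59.6% changed between MK2206 and DMSO, which a technical difference between the libraries could give. A trend with transcript length or GC content is argued against as the whole cause, since 7814 genes passed after each library's trends were removed and the DNA replication list kept a median log2 change of -1.47 (95% bootstrap interval -1.58 to -1.35). Depth is argued against too. The libraries of different groups closest in depth, at a ratio of 1.06, differed by at least 2-fold in 535 genes, and the libraries of 1 group farthest apart in depth, at a ratio of 1.43, in 82 genes. The treatment, which the labels name, stays open as an untested explanation.

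The tested histone genes rose while DNA replication genes fell, although in dividing cells both are made together in S phase. The libraries were made by selecting polyadenylated RNA, so these values may not follow the main histone transcripts, which carry no poly(A) tail. Of the 19 listed histone genes 7 lay below 1 FPKM in every library and were not tested. One candidate explanation is that more RNA without a poly(A) tail entered the MK2206 libraries. Under it, other such RNAs would rise by about as much as the histone genes, whose median log2 change was 1.03 (95% bootstrap interval 0.787 to 1.246). The 74 SNORA, SCARNA, RMRP and RPPH1 genes tested had a median log2 change of -0.34 (95% bootstrap interval -0.45 to 0.0045), with 4 up and 13 down. This argues against that explanation only if the drug did not lower these RNAs themselves, which was not tested. A further caution is that most of these RNAs are short and their estimates vary widely. A rise of histone transcripts that carry a poly(A) tail, and shared reads between histone copies, stay open and were not tested.

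Small RNA genes had the largest changes. A candidate explanation is that estimates for transcripts shorter than a library fragment are unstable. In 142 such genes the median difference between libraries of the same group was 9.09 times the median in simulated counts of reads over the full transcript. In 11428 longer genes it was 1.87 times, a ratio of 4.85 (95% bootstrap interval 3.82 to 7.06). It was 4.88 times in the 55 small RNA genes with no library listed under 0.01 FPKM. This is in line with that explanation, but other sources of spread between libraries would give the same, and whether any single small RNA gene changed with the drug stays open.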
